A study of Caenorhabditis elegans with 33 samples.

How the data were processed

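RNA from whole *Caenorhabditis elegans* (strain N2) was sequenced in 33 libraries, which the labels place in 11 groups of 3 by the bacteria fed to the animals. 1 group ate BW25113, a laboratory strain of *Escherichia coli*, and each of the other 10 ate a different mutant. The groups were taken from the sample titles. In 1 group the titles read yjgU and the treatment labels read yigU, so the name in the titles is used and the identity of that mutant is uncertain. Per the labels, total RNA was extracted with Trizol from synchronized adults and sequenced on a DNBSEQ instrument. The day of adulthood, the number of animals per library, the strandedness of the libraries and the origin of the replicates (separate cultures or repeated extractions) are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

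For each library the authors deposited 1 table of 18811 gene symbols with an estimated read count (expected count) and a TPM value (transcript abundance scaled to a fixed total), per the file headers. HISAT, StringTie, Bowtie2 and the genome build WBcel235 are named in the submitters' processing notes, with no roles or versions. The tool that made the counts, its treatment of reads shared between genes, and the annotation release are not given in the sources used here. Between 7.78% and 10.0% of the deposited expected counts per library were not whole numbers, and these were rounded before testing. The TPM values deposited by the authors were not used in any test. Symbols were matched to the Ensembl release 115 annotation of WBcel235, 18102 directly and 536 by locus name, and 173 were unmatched. 5 symbols that look like dates were kept in the tests and are not named.

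Totals ranged from 20.5 M to 22.7 M expected counts per library (median 22.3 M). No pair of replicates looked like 1 library deposited more than once: over genes with at least 10 counts in a pair, the smallest chi-square per degree of freedom among 33 pairs was 15.7. Genes with low counts were left out with filterByExpr of edgeR, which kept 14696 genes and left out 4115, holding 0.0197% of all counts. Libraries were scaled with TMM factors (0.661 to 1.90), and the 33 libraries were fitted together by diet in edgeR 4.0.16 with the quasi-likelihood test (common dispersion 0.198). Each mutant was contrasted with BW25113, the mean of the 10 mutants was contrasted with BW25113, and an F test asked which genes differ among the mutants. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Values per gene are CPM (counts per 1e6) on TMM-scaled library sizes, and SE is the absolute log2 fold change divided by the square root of F.

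37 gene lists for tissues, stages, pathways and gene families were written before the data were examined, and so were the tests, the rule for naming genes and the first set of alternative analyses. The 35 lists with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and also with an estimated correlation. They were also tested on their own with fry, for changes in 1 direction and, in its mixed test, in either. Adjustment ran over 350 tests, all lists and all 10 comparisons together. Counts of list members that passed are given over all genes tested and, where stated, adjusted over the list alone. Fitted fold changes of genes at 0 in 1 whole group are not bounds. Setting them to the bound given by a floor of 3 counts over the group changed list medians by 0 and moved the median size of the called changes from 2.64 to 2.64 in torY and from 3.26 to 3.24 in yccU.

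Genes were named by a fixed rule. Named were the 6 largest rises and 6 largest falls with a symbol of letters and a number, and the largest rise and fall of any symbol, among called genes with a mean of at least 5 CPM over the 33 libraries and no overlap between the 3 mutant and 3 control libraries. Also named, with no such demand on level or overlap, were up to 3 called members with the lowest p in each list that passed its set test, and every called member of the lists for the oxygen and social feeding circuit, dopamine, and serotonin, octopamine and tyramine. Genes named for comparisons without calls were chosen after their values were seen, as those with the lowest unadjusted p among genes with such a symbol and a mean of at least 5 CPM.

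The fit was tested on simulated counts with 200 genes changed. In the simulated crl comparison it recovered 10.0% of 50 genes changed by 2-fold, 62.0% at 4-fold, 88.0% at 8-fold and 96.0% at 16-fold, with 8 calls among 14496 unchanged genes. In the simulated torY comparison it recovered 8.0%, 66.0%, 90.0% and 94.0%, with 4 such calls. All 10 comparisons share the same 3 control libraries, so overlaps between them are given beside 20 simulations of unchanged groups against those controls. Genes varied independently of each other in these simulations.

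Alternative analyses chosen beforehand were DESeq2 1.42.0, RLE factors in place of TMM, no filter on low counts, the replicate number as an added factor, a fit of the 6 libraries of each comparison alone, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out purH replicate 1 and yccU replicate 2 together, surrogate variables (sva 3.50.0), the level of the larval and molting list as a covariate, and other groupings of the mutants. Also chosen later were the list tests and the test among mutants without each library in turn, and every alternative of the overlap, including separate reference groups. An alternative pseudocount was planned for files without counts and was not needed. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.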

Results

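Adult worms were fed BW25113 bacteria or 1 of 10 bacterial mutants, and gene expression in whole animals was compared between the diets. According to the series title, the study concerns variation in the genes of gut bacteria and social behavior of the host. Each of the 11 diets had 3 libraries, with totals of 20.5 M to 22.7 M (M, 1e6) expected counts and between 15309 and 16914 genes above 0. Across genes, Pearson correlations of log2 CPM between replicates ranged from 0.798 to 0.993 with a median of 0.952 (genes are not independent replicates). The lowest value was between purH replicates 1 and 2, and purH replicate 1 also had 0.846 with replicate 3, while purH replicates 2 and 3 had 0.966. The biological coefficient of variation estimated from all libraries was 44.5%. Bacterial transcripts were not analysed here, so the mutated genes themselves could not be used to check the labels.

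The diets fell apart in 1 main way: lists of cuticle and molting genes were higher in torY and yccU than in BW25113, clearly so in the 3 torY libraries and in 2 of the 3 yccU libraries. The number of called genes was 2193 in torY and 385 in yccU, and 0 in each of the other 8 mutants by edgeR in the fit of all libraries. A fit of the 6 libraries of a comparison alone also called genes in yjgU, as given below.

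**Figure D1:**
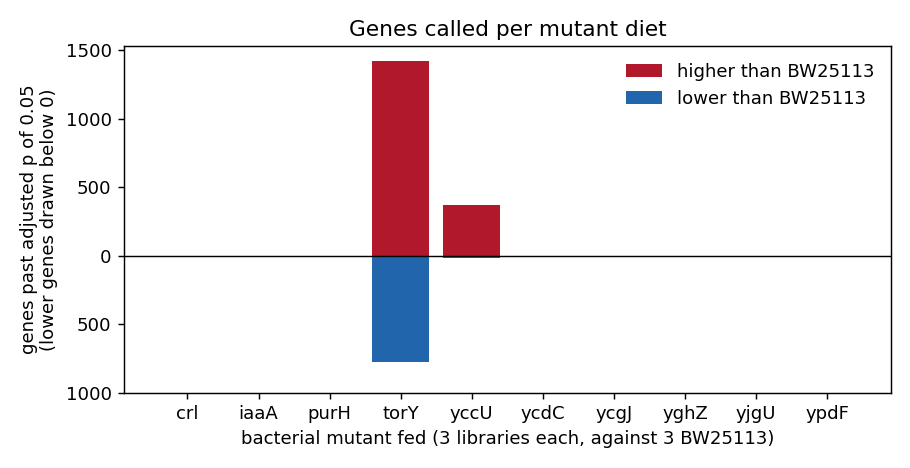
Number of genes past an adjusted p of 0.05 in each mutant against BW25113 (vertical axis, genes; horizontal axis, bacterial mutant), with genes that rose drawn above 0 in red and genes that fell drawn below 0 in blue. torY had 1420 rises and 773 falls, yccU had 367 and 18, and the other 8 mutants had 0 by edgeR in the fit of all libraries, where DESeq2 called between 0 and 4.

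Worms fed torY were compared with worms fed BW25113 to ask what the torY mutation in the bacteria, a gene for a cytochrome of anaerobic respiration, changed in the host. The largest changes are named among called genes with a mean of at least 5 CPM over the 33 libraries and no overlap between the 2 groups. The rises were in structural genes of the cuticle, the collagen coat that nematodes rebuild at each molt. The collagen gene lon-3 (chromosome V, 12197437 to 12198645) stood at 123 ± 65.7 CPM in torY and 1.12 ± 0.325 in BW25113 (SD, n = 3 each), a log2 fold change of 6.76 (SE 1.45, adjusted p = 0.0118). The collagens rol-6 (chromosome II, 8733050 to 8734239; log2 fold change 6.39, SE 1.46), bli-2 (II, 5651394 to 5652434; 6.38, SE 1.597), col-41 (X, 15175032 to 15176481; 6.27, SE 1.34), sqt-2 (II, 23325 to 24458; 5.92, SE 1.42) and rol-8 (II, 7544108 to 7545335; 5.90, SE 1.44) followed. The largest falls among such genes were also partly collagens: col-74 (II, 5830374 to 5832022) fell by 8.42 (SE 2.85), although its 3 control libraries ranged from 0.413 to 55.8 CPM, dpy-14 (I, 6843589 to 6845142) fell by 6.59 (SE 1.699), and hch-1 (X, 14696411 to 14699977), a protease that frees the embryo from the eggshell, fell by 5.86 (SE 1.46). Next came col-121 (IV, 9394873 to 9396218; -5.64, SE 1.75), dpy-17 (III, 5107330 to 5108492; -5.63, SE 1.53) and the linker histone gene hil-7 (IV, 6646312 to 6646972; -5.59, SE 1.67). In every gene named for torY or yccU in these comparisons, the 3 mutant libraries lay on 1 side of the 3 control libraries, which the naming rule itself demanded of the largest rises and falls. Such a separation was found for 47.3% of all genes tested in torY and 34.4% in yccU, where chance gives 10% on average. In the other mutants it ranged from 2.96% (ypdF) to 25.3% (yjgU).

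Of 154 cuticle collagens tested in torY, 76 rose, 5 fell and 73 did not pass, and adjusted over the list alone 88 rose and 8 fell. Their median log2 fold change was 2.93 (camera adjusted p = 2.02e-12 at the preset correlation, adjusted p = 0.962 with an estimated correlation). By lowest p the leading members were dpy-9 (IV, 257403 to 259204), at 82.5 ± 48.7 CPM against 2.80 ± 0.0986 (SD, n = 3 each), col-110 (IV, 4608201 to 4609668; log2 fold change 4.49, SE 0.89) and col-111 (IV, 4655791 to 4657974; 4.29, SE 0.86). Of 35 larval and molting genes, 14 of which are also in the collagen list, 18 rose, 0 fell and 17 did not pass in the edgeR test, and adjusted over the list alone 20 rose and 0 fell (median 2.27, adjusted p = 1.1e-08, and adjusted p = 0.962 with an estimated correlation). This was the only list and comparison that passed the directional test of fry (adjusted p = 0.0406), while 14 of 350 passed its mixed test, which asks for changes in either direction (adjusted p = 0.000979 for this list in torY). Besides dpy-9, its leading members were grl-5 (V, 4412748 to 4414663), a secreted ground-like protein that went from 3.25 ± 3.02 to 58.8 ± 23.5 CPM, and the collagen dpy-8 (X, 5148804 to 5150476; log2 fold change 5.51, SE 1.19). The grl-5 level was 6.70 in BW25113 replicate 1 and 1.96 and 1.09 in replicates 2 and 3. The mean level of the larval and molting list, on a log2 scale relative to all 33 libraries, was 2.13 ± 0.66 in torY and -0.64 ± 0.43 in BW25113 (SD, n = 3 each).

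Lists of germline and embryo genes also passed in torY at the preset correlation, although most of their members were not called. Of 29 sperm genes, 7 rose, 0 fell and 22 did not pass, and adjusted over the list alone 28 rose and 0 fell, with a median of 2.84 (adjusted p = 1.81e-07 at the preset correlation). The sperm toxin gene peel-1 (I, 2352835 to 2356238) was at 1.91 ± 0.583 CPM against 0.0539 ± 0.0518, and fer-1 (I, 8623012 to 8631202), needed for membrane fusion in sperm, was at 5.12 ± 2.86 against 0.741 ± 0.394 (SD, n = 3 each). Of 26 embryo genes, 0 rose, 10 fell and 16 did not pass, and adjusted over the list alone 20 fell (median -1.79, adjusted p = 8.23e-08). Among them sdc-2 (X, 11522707 to 11533450), a gene of dosage compensation, fell by 2.02 (SE 0.42) and the transcription factor gene ztf-11 (I, 9904303 to 9910545) fell by 2.73 (SE 0.66). Of 36 oocyte and eggshell genes, 3 fell, 0 rose and 33 did not pass, and adjusted over the list alone 2 fell (median -1.099, adjusted p = 7.76e-07). These were chs-1 (I, 7554855 to 7559916), the chitin synthase of the eggshell (-1.55, SE 0.40), egg-2 (III, 7058527 to 7060583; -1.17, SE 0.35) and the germline receptor gene glp-1 (III, 9092241 to 9099698; -1.59, SE 0.54). None of the 6 vitellogenins passed over all genes by edgeR, and adjusted over the list alone 3 fell (median -1.496, adjusted p = 0.0166). Of 30 histone genes, 7 fell, 0 rose and 23 did not pass, and adjusted over the list alone 10 fell and 2 rose (median -0.75, adjusted p = 0.0392). By lowest p the first were his-46 (-1.87, SE 0.50) and his-45 (-1.88, SE 0.54), followed by his-24 (X, 14490094 to 14491119) at 104.1 ± 69.7 CPM against 729 ± 275. With an estimated correlation the adjusted p = 0.962 for each of these lists. The vitellogenins lost their call without torY replicate 2 (adjusted p = 0.0709). The histones lost theirs without BW25113 replicate 1 (adjusted p = 0.110) or 2 (0.150) and without torY replicate 2 (0.202) or 3 (0.0882).

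Lists of families outside the cuticle also had called members in torY, where 2193 of the 14696 genes tested were called. Of 273 F-box and MATH-BATH genes, which encode substrate adaptors for protein degradation, 65 fell, 4 rose and 204 did not pass, and adjusted over the list alone 81 fell and 7 rose (median -0.57, adjusted p = 2.26e-06). By lowest p the first was fbxb-106 (II, 2762408 to 2763507), at 0.0146 ± 0.0253 CPM against 0.687 ± 0.218. Of 127 C-type lectins and lysozymes, 20 rose, 5 fell and 102 did not pass, and adjusted over the list alone 27 rose and 9 fell (median 0.44, adjusted p = 0.0408). In that list clec-266 (X, 6617393 to 6622915) fell by 4.52 (SE 0.99) and clec-4 (II, 12578331 to 12581113) rose by 2.66 (SE 0.61). Of 31 genes of the p38 pathogen response, 14 of which are also lectins or lysozymes of that list, 4 rose and 0 fell, and adjusted over the list alone 4 rose (median 0.55, adjusted p = 0.0408). After clec-4 came the lysozyme gene lys-2 (V, 10280307 to 10281474), at 352 ± 107 CPM against 113.9 ± 65.4. Of 154 xenobiotic enzymes, 16 rose, 1 fell and 137 did not pass, and adjusted over the list alone 11 rose and 1 fell (median 0.65, adjusted p = 0.00858), led by gst-6 (II, 4879891 to 4881105; 2.28, SE 0.50) and cyp-33C8 (V, 3800782 to 3803542; 3.36, SE 0.81). Of 21 hypoxia response genes, 5 rose, 0 fell and 16 did not pass, and adjusted over the list alone 5 rose (median 0.56, adjusted p = 0.0489). Its leading member was lin-42 (II, 1233236 to 1252359; 2.93, SE 0.70), a period homolog whose expression cycles with larval molts, followed by F22B5.4 (II, 8449710 to 8452742; 2.22, SE 0.55) and phy-2 (IV, 12211097 to 12215987; 1.26, SE 0.34), a prolyl hydroxylase that modifies collagen. With an estimated correlation the adjusted p = 0.962 for each of these lists. Of these calls only that of the F-box and MATH-BATH genes stayed without each of the 6 libraries. The lectin and lysozyme list lost its call without BW25113 replicate 3 (adjusted p = 0.0972), and the xenobiotic enzymes without torY replicate 2 (0.111). The p38 list lost its call without BW25113 replicate 3 (0.286), torY replicate 1 (0.0758) or torY replicate 2 (0.0629), and the hypoxia list without BW25113 replicate 1 (0.0821), BW25113 replicate 3 (0.0928) or torY replicate 1 (0.0819).

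Lists of the nervous system also had called members in torY, where 2193 of the 14696 genes tested were called. None of the lists in this paragraph held called genes more often than all genes tested did. Of 107 neuropeptide genes, 12 rose, 0 fell and 95 did not pass, and adjusted over the list alone 12 rose (median 0.79, adjusted p = 8.23e-08, and adjusted p = 0.962 with an estimated correlation). Their leading members were nlp-25 (V, 19606180 to 19608419; 3.68, SE 0.75), nlp-67 (X, 16184369 to 16185722; 2.57, SE 0.62) and nlp-33 (V, 11147346 to 11147737; 2.06, SE 0.50), the last of which is also known as an antimicrobial peptide of the epidermis. Of 16 dopamine genes, 2 rose, 0 fell and 14 did not pass, and adjusted over the list alone 1 rose (median 0.91, adjusted p = 0.0164, adjusted p = 0.0593 without torY replicate 1, and adjusted p = 0.962 with an estimated correlation). These were bas-1 (III, 5612274 to 5614660), the decarboxylase that makes dopamine and serotonin, at 19.2 ± 4.14 against 10.5 ± 0.146 CPM, and the amine oxidase gene amx-2 (I, 12759587 to 12764960), at 22.1 ± 4.75 against 8.68 ± 2.41 (SD, n = 3 each). Of 22 genes of the oxygen and social feeding circuit, 1 rose, 0 fell and 21 did not pass, and adjusted over the list alone 0 passed by edgeR. The gene that rose was lite-1 (X, 6226126 to 6230769), which encodes a light receptor, at 1.89 ± 0.651 against 0.706 ± 0.552 CPM (log2 fold change 1.404, SE 0.46, adjusted p = 0.041, and 2.27 without BW25113 replicate 3). Of 17 genes for serotonin, octopamine and tyramine, 0 passed by edgeR, and the list had an adjusted p = 0.477 at the preset correlation.

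The edgeR test called 2193 genes in torY (1420 up, 773 down), with 5371 at an unadjusted p under 0.05, and DESeq2 called 3376. The call count depended on single libraries: it was 0 without BW25113 replicate 2 (4017 at an unadjusted p under 0.05), 753 and 608 without BW25113 replicates 1 and 3, and 542 and 153 without torY replicates 1 and 3. It was 4246 when the 6 libraries were fitted alone, and 0 when the level of the larval and molting list was a covariate (0.708% of the genes tested at an unadjusted p under 0.05).

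Worms fed yccU had a similar list of leading genes. By the same rule, the largest rises were lon-3 at 88.9 ± 63.3 CPM against 1.12 ± 0.325 (SD, n = 3 each; log2 fold change 6.30, SE 1.43, adjusted p = 0.0318), bli-2 (6.03, SE 1.57), rol-6 (5.91, SE 1.43), col-79 (II, 10703613 to 10704572; 5.42, SE 1.41), col-41 (5.32, SE 1.28) and sqt-2 (5.25, SE 1.38). The largest falls among such genes were smaller: ZK1053.4 (I, 13241655 to 13244730) fell by 2.52 (SE 0.66), the transcription factor gene hlh-2 (I, 7190788 to 7193920) fell by 1.80 (SE 0.48), the histone demethylase gene utx-1 (X, 8557146 to 8563238) fell by 1.59 (SE 0.42), and the zinc finger gene ccch-5 (IV, 14919610 to 14920486) fell by 1.47 (SE 0.40). Libraries of yccU differed among themselves: lon-3 was at 133 and 118 CPM in replicates 1 and 3 and at 16.3 in replicate 2, and the larval and molting list stood at 2.39, 2.21 and -0.07 in the same order.

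Of the 154 cuticle collagens, 38 rose, 0 fell and 116 did not pass in yccU, and adjusted over the list alone 84 rose and 7 fell (median 2.52, adjusted p = 5.57e-11). Of 35 larval and molting genes, 12 rose, 0 fell and 23 did not pass, and adjusted over the list alone 19 rose (median 1.95, adjusted p = 5.39e-07). In both lists dpy-9 had the lowest p (4.39, SE 0.91), followed in the molting list by grl-15 (III, 12232632 to 12236014; 5.15, SE 1.14) and the hedgehog-related qua-1 (II, 8198803 to 8204004; 3.29, SE 0.75), and in the collagen list by col-111 (3.94, SE 0.85) and col-110 (4.07, SE 0.88). Of 29 sperm genes 1 rose, namely peel-1 at 1.68 ± 0.784 against 0.0539 ± 0.0518 CPM, and adjusted over the list alone 26 rose (median 2.68, adjusted p = 4.41e-08). Of 26 embryo genes 1 fell, namely sdc-2 (-1.47, SE 0.41), and adjusted over the list alone 9 fell (median -1.44, adjusted p = 2.71e-08). Of 21 hypoxia response genes 3 rose, namely phy-2 (1.49, SE 0.35), F22B5.4 (2.34, SE 0.55) and cysl-1 (X, 9952579 to 9954533; 1.29, SE 0.33), and adjusted over the list alone 6 rose (median 0.55, adjusted p = 0.0141). Of 107 neuropeptide genes 2 rose, nlp-25 (3.86, SE 0.75) and nlp-33 (1.95, SE 0.50), and adjusted over the list alone 2 rose (median 0.52, adjusted p = 0.00012). Of 273 F-box and MATH-BATH genes 2 fell, fbxb-111 (II, 2773926 to 2775004; -3.61, SE 0.82) and fbxb-19 (II, 1688181 to 1689181; -3.99, SE 1.00, and -6.80 without yccU replicate 2), and adjusted over the list alone 1 fell (median -0.48, adjusted p = 1.33e-06). Of 31 genes of the p38 pathogen response 1 rose, clec-4 (2.17, SE 0.60), and adjusted over the list alone 1 rose (median 0.50, adjusted p = 0.0197). By edgeR 0 genes passed among the vitellogenins (median -1.299, adjusted p = 0.0169), oocyte and eggshell genes (median -0.92, adjusted p = 1.86e-06), histones (median -0.67, adjusted p = 0.0323) and dopamine genes (median 0.63, adjusted p = 0.027), and adjusted over the list alone 0 passed in each. With an estimated correlation the adjusted p = 0.962 for every list in yccU that passed at the preset correlation. The dopamine list lost its call without yccU replicate 1 (adjusted p = 0.0638), and the p38 list without that library (0.0635) or BW25113 replicate 3 (0.246). The histones lost theirs without BW25113 replicate 1 (0.105) or 2 (0.158) or yccU replicate 3 (0.189). The mean of the oocyte and eggshell list differed from BW25113 by -0.89, and by -0.60 without yccU replicate 1.

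In yccU the edgeR test called 385 genes (367 up, 18 down), with 3952 at an unadjusted p under 0.05, while DESeq2 called 1813, of which 1558 rose and 255 fell. The edgeR count was 2171 without yccU replicate 2 and 0 without any other 1 of the 6 libraries (BW25113 replicates 1, 2 and 3, yccU replicates 1 and 3), with between 2341 and 3349 genes at an unadjusted p under 0.05 in those 5 fits. It was 2003 when the 6 libraries were fitted alone, 209 with no filter on low counts, and 0 when the level of the larval and molting list was a covariate (198 at an unadjusted p under 0.05).

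**Figure D2:**
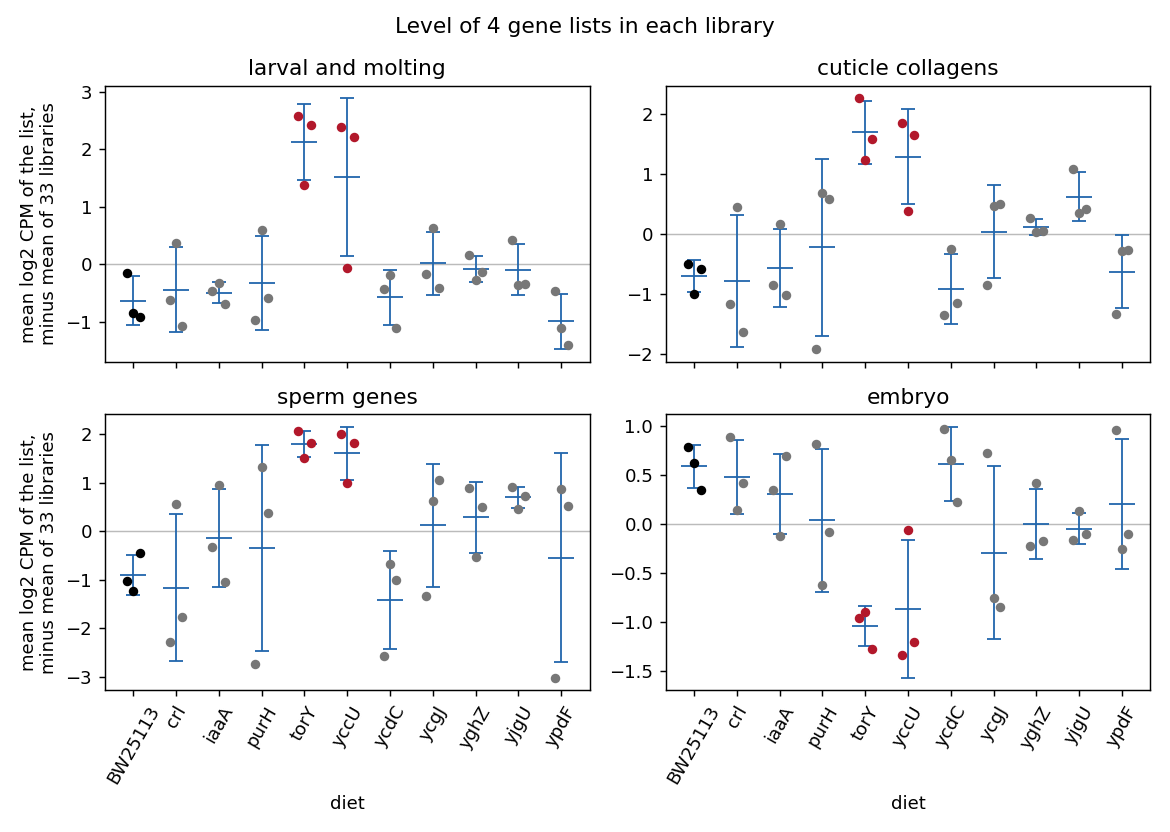
Mean log2 CPM of 4 gene lists in each library, relative to the mean of the 33 libraries (vertical axis, log2 CPM), by diet (horizontal axis). Points are libraries (black, BW25113; red, torY and yccU; grey, other mutants) and blue bars are mean ± SD (n = 3). For the larval and molting list the torY libraries lie between 1.37 and 2.58, yccU has 2 libraries above 2.2 and 1 at -0.07, and the BW25113 libraries lie between -0.92 and -0.15.

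Calls of torY and yccU overlapped. In both, 365 genes rose and 17 fell, and 0 changed in opposite directions among the edgeR calls. Independent lists of those sizes would share 35.5 rises and 0.947 falls among 14696 genes. Across genes, log2 fold changes of these mutants correlated at r = 0.957, where 20 simulations of unchanged groups sharing the 3 controls gave 0.507 on average (genes are not independent replicates). Their covariance was 2.102 against 0.231 simulated, a difference of 1.87. The 3 controls cannot be divided into parts of at least 2 libraries each, so part of the excess may come from the shared controls. The simulated genes varied independently of each other, so the simulations hold no variation that many genes share within a library. For ycgJ and yghZ, which had 0 calls by edgeR, r was 0.835. An r above the simulated level therefore did not require calls. Over all 45 pairs of mutants r ranged from 0.182 to 0.957, simulated means ranged from 0.504 to 0.523, and 42 pairs had a covariance above the simulated one. In a comparison chosen after seeing the data, torY was set against crl, iaaA, purH and ycdC, and yccU against ycgJ, yghZ, yjgU and ypdF, so that no library was shared: 346 of 2465 and 373 rises were shared (62.6 if independent), 4 of 1978 and 4 falls were shared (0.538 if independent), and r was 0.841. The count of 382 shared calls was 0 when any 1 BW25113 library (replicate 1, 2 or 3) was left out. In each of those fits yccU itself had 0 calls, so no call could be shared. These counts therefore do not show how alike torY and yccU were.

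The 10 mutants were also compared with each other, without BW25113. By edgeR 376 genes differed among them (3051 at an unadjusted p under 0.05), and DESeq2 gave 2143. Of the 376, 320 were highest in torY and 24 in yccU, while 172 were lowest in ycdC and 69 in ypdF. Among the 8 mutants other than torY and yccU, 0 genes differed by edgeR (545 at an unadjusted p under 0.05). Between torY and yccU 0 genes differed (62 at an unadjusted p under 0.05). Against the mean of those 8, edgeR called 3760 genes in torY (2224 up, 1536 down) and 1141 in yccU (1070 up, 71 down). All of these groupings were chosen after seeing the data and were not run in DESeq2. The 8 were set apart by the outcome, so these counts are not independent support for a difference. The count of 376 moved to 106 and 129 without torY replicates 1 and 3, to 185, 957 and 191 without yccU replicates 1, 2 and 3, to 568 and 857 without purH replicates 1 and 2, and to 213 without yghZ replicate 2. It was 0 with the level of the larval and molting list as a covariate (366 at an unadjusted p under 0.05).

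For the other 8 mutants no gene passed over all genes tested by edgeR, so the genes below are described by their values, and lists by the direction of their set test at the preset correlation. If nothing changed, a fraction of 0.05 of the genes tested would be expected at an unadjusted p under 0.05. The observed share was below that in crl (1.02%), iaaA (1.12%), ypdF (1.32%), ycdC (4.64%) and ycgJ (4.74%). It was above that in purH (7.17%), yghZ (6.71%) and yjgU (6.49%). Over all 10 mutants 45 list tests kept their call whichever 1 of their 6 libraries was left out, and 74 lost it at least once. The paragraphs on single mutants below therefore describe only passing lists that kept their call each time, a choice made after seeing the data. Where a left-out library moved the difference of a list mean from BW25113 by over 1.5 times, that library is named with both values. Every list named for these 8 mutants had an adjusted p = 0.962 with an estimated correlation, and 0 of 350 tests passed with it.

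With purH, a mutant in purine synthesis, argk-1 (V, 16103894 to 16105952), which encodes an arginine kinase, was at 56.3 ± 38.5 CPM against 12.7 ± 3.31 in BW25113 (SD, n = 3 each; log2 fold change 2.15, SE 0.62). The caenacin gene cnc-8 (X, 10306595 to 10306951) followed at 30.9 ± 20.3 against 11.39 ± 2.09. Its level was 54.001 in purH replicate 1 and 16.16 and 22.4 in replicates 2 and 3. Then came the glyoxylate cycle gene icl-1 (V, 724332 to 728004) at 195 ± 103 against 631 ± 428. The controls held 1070 in BW25113 replicate 1 and 608 and 215 in replicates 2 and 3. Next was cth-1 (V, 16100680 to 16102750), an enzyme of cysteine synthesis, at 111 ± 68.2 against 30.1 ± 9.68. In purH replicate 1 cth-1 was at 35.1, within the BW25113 range of 20.5 to 39.8, and at 131 and 167 in replicates 2 and 3. Of 12 lists that passed in purH 2 kept their call without each library, both lower than in BW25113. These were the vitellogenins (median -1.103, all 6 members lower, adjusted p = 2.03e-05) and the oocyte and eggshell genes (median -0.80, 33 of 36 lower, adjusted p = 9.03e-11). Without purH replicate 1 the vitellogenin difference went from -1.66 to -0.60 (adjusted p = 0.032) and the oocyte difference from -0.95 to -0.37 (adjusted p = 0.000592). The 33 purine and pyrimidine genes had a median of 0.03 (adjusted p = 0.712). In edgeR 0 genes were called, with 1054 at an unadjusted p under 0.05, and DESeq2 called 1, gtf-2H2C, which was at 0 in 17 of the 33 libraries. Adjusted over the list alone, 1 neuropeptide gene and 2 xenobiotic enzymes passed.

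With yjgU, the hedgehog-related wrt-4 (X, 15752257 to 15757269) was at 11.5 ± 6.63 CPM against 1.72 ± 0.442 (SD, n = 3 each; log2 fold change 2.73, SE 0.74). Replicate 1 of yjgU had 19.1 and replicates 2 and 3 had 7.49 and 7.79. Next were the astacin protease gene nas-30 (I, 938483 to 947710) at 12.4 ± 2.33 against 2.94 ± 0.927, spin-1 (V, 12114993 to 12117443) at 12.78 ± 1.21 against 5.98 ± 1.096, and the kynureninase gene kynu-1 (X, 6106927 to 6109338) at 32.3 ± 2.38 against 18.5 ± 3.49. Cuticle collagens were higher (median 1.57, 126 of 154 higher, adjusted p = 7e-15), as were sperm genes (median 1.701, 29 of 29 higher, adjusted p = 1.57e-08) and neuropeptides (median 0.27, adjusted p = 4.29e-05), and F-box and MATH-BATH genes were lower (median -0.50, 217 of 273 lower, adjusted p = 7.33e-07), as were embryo genes (median -0.68, 23 of 26 lower, adjusted p = 2.66e-05). The neuropeptide difference went from 0.33 to 0.20 without yjgU replicate 1 (adjusted p = 0.0451), and the F-box difference from -0.41 to -0.24 without BW25113 replicate 1 (adjusted p = 0.00258). No overlap between the 3 yjgU and 3 control libraries was found for 25.3% of genes, where chance gives 10% on average. In the other mutants with 0 calls by edgeR this share ranged from 2.96% (ypdF) to 14.9% (yghZ). Genes are not independent, so it can lie far from 10% by chance. The count by edgeR was 0, with 954 at an unadjusted p under 0.05, and DESeq2 called 1, T23F2.13, which was at 0 in 19 of the 33 libraries. A fit of the 6 libraries alone called 523 genes (451 up, 72 down).

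With yghZ, the catalase gene ctl-2 (II, 14299556 to 14302027) was at 34.6 ± 6.04 CPM against 78.5 ± 41.8 (SD, n = 3 each; log2 fold change -1.18, SE 0.32), grd-14 (X, 8500021 to 8501037) at 36.9 ± 25.6 against 12.2 ± 3.45 and icl-1 at 186 ± 60.3 against 631 ± 428. The grd-14 level was 65.5 in yghZ replicate 1 and 16.21 and 28.8 in replicates 2 and 3. The icl-1 level was 1070 in BW25113 replicate 1, and 608 and 215 in replicates 2 and 3. Vitellogenins (median -1.17, adjusted p = 0.000919), body muscle genes (median -0.63, 19 of 20 lower, adjusted p = 0.000272) and embryo genes (median -0.58, 24 of 26 lower, adjusted p = 0.000239) were lower. Without yghZ replicate 1 the vitellogenin difference went from -1.28 to -0.77 (adjusted p = 0.00798) and the body muscle difference from -0.58 to -0.33 (adjusted p = 0.00277). Sperm genes (median 1.32, adjusted p = 3.84e-05) and collagens (median 1.04, adjusted p = 0.000212) were higher. Adjusted over the list alone, 4 DAF-16 targets and 1 gene of oxidative stress and detoxification fell. In edgeR 0 genes were called, with 986 at an unadjusted p under 0.05, and DESeq2 called 0.

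With ycdC, whose gene encodes a regulator of pyrimidine breakdown, the lowest p belonged to pfd-5 (III, 7198151 to 7198884), at 84.1 ± 18.5 CPM against 44.4 ± 4.26, and to pbs-4 (I, 3908747 to 3909701), at 175 ± 31.0 against 97.0 ± 16.39 (SD, n = 3 each; adjusted p = 0.744 for each). Body muscle genes (median -0.70, adjusted p = 4.64e-07) and endoplasmic reticulum stress genes (median -0.47, adjusted p = 0.000123) were lower. The body muscle difference went from -0.75 to -0.36 without ycdC replicate 2 (adjusted p = 0.000186) and to -1.16 without ycdC replicate 3 (adjusted p = 6.83e-08). The endoplasmic reticulum stress difference went from -0.52 to -0.24 without ycdC replicate 2 (adjusted p = 0.0428). The count by edgeR was 0, with 682 at an unadjusted p under 0.05, and DESeq2 called 0. Without ycdC replicate 3, edgeR called 1 gene, ubh-2, at 4.83 CPM over the 3 ycdC libraries and 10.0 in BW25113.

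With ycgJ, argk-1 was at 78.2 ± 24.7 CPM against 12.7 ± 3.31 (SD, n = 3 each; log2 fold change 2.62, SE 0.63) and cyp-33C8 at 35.2 ± 36.9 against 4.48 ± 1.65. That mean was carried by ycgJ replicate 2, at 77.7 against 16.6 and 11.36 in replicates 1 and 3. Embryo genes were lower (median -0.78, 23 of 26 lower, adjusted p = 1.1e-08), as were histones (median -0.96, 27 of 30 lower, adjusted p = 1.03e-13). Oocyte and eggshell genes were lower as well (adjusted p = 3.84e-05), and intracellular pathogen response genes were higher (median 0.90, adjusted p = 0.000212). The embryo difference went from -0.88 to -1.39 without ycgJ replicate 1 (adjusted p = 1.05e-13). Without ycgJ replicate 2 the oocyte difference went from -0.52 to -0.25 (adjusted p = 0.0253) and the pathogen response difference from 0.74 to 0.39 (adjusted p = 0.0307). In edgeR 0 genes were called, with 697 at an unadjusted p under 0.05, and DESeq2 called 2, Y38C1AA.6 and F48C1.6, which were at 0 in 19 and 12 of the 33 libraries.

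With crl, a regulator of the bacterial stationary phase, the cathepsin B gene cpr-4 (V, 6614674 to 6615851) was at 841 ± 240 CPM against 1926 ± 672 (SD, n = 3 each; log2 fold change -1.196, SE 0.41), and irg-5 (V, 13737010 to 13738474), an infection response gene, at 9.14 ± 6.05 against 2.83 ± 0.864. The irg-5 level was 16.097 in crl replicate 2 and 5.09 and 6.23 in replicates 1 and 3. Of 9 lists that passed in crl 1 kept its call without each library, the body muscle genes, which were lower (median -0.47, 18 of 20 lower, adjusted p = 0.000504). The count by edgeR was 0, with 150 at an unadjusted p under 0.05, and DESeq2 called 4, Y38C1AA.6, T14G10.8, gtf-2H2C and Y62E10A.24, which were at 0 in 17 to 20 of the 33 libraries.

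With iaaA, argk-1 was at 61.8 ± 32.5 CPM against 12.7 ± 3.31 (SD, n = 3 each; log2 fold change 2.28, SE 0.62) and cpr-4 at 898 ± 265 against 1926 ± 672. Nuclear respiratory chain genes were lower (adjusted p = 0.000111). Their difference went from -0.27 to -0.16 without BW25113 replicate 1 (adjusted p = 0.0283) or iaaA replicate 1 (adjusted p = 0.0234) and to -0.42 without BW25113 replicate 3 (adjusted p = 3.00e-06). In edgeR 0 genes were called, with 1.12% of the genes tested at an unadjusted p under 0.05, and DESeq2 called 0.

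With ypdF, kynu-1 was at 32.0 ± 2.67 CPM against 18.5 ± 3.49 (SD, n = 3 each; log2 fold change 0.79, SE 0.24) and the cytochrome gene cyp-35A2 (V, 7362319 to 7364182) at 11.5 ± 3.26 against 33.8 ± 2.39. Of 13 lists that passed in ypdF 2 kept their call without each library, the ribosomal protein genes and the histones, which are described below. The count by edgeR was 0, with 194 at an unadjusted p under 0.05, and DESeq2 called 0.

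Some lists moved alike in many mutants. Ribosomal protein genes were lower in 7 mutants at the preset correlation, and 5 of these kept the call without each of their libraries: yghZ (median -0.80, 70 of 81 lower, adjusted p = 5.62e-13), ycdC (median -0.68), ycgJ (median -0.66), ypdF (median -0.52) and iaaA (median -0.48). In purH (median -0.27, adjusted p = 7.33e-07) the call was lost without purH replicate 1 (adjusted p = 0.294). In crl it was lost without BW25113 replicate 1 (adjusted p = 0.102) or crl replicate 3 (0.359). The ribosomal difference in iaaA went from -0.51 to -0.23 and -0.79 without iaaA replicates 1 and 3, in ycgJ from -0.71 to -0.45 and -1.16 without ycgJ replicates 2 and 3, and in ypdF from -0.45 to -0.27 without ypdF replicate 2. Histone genes were lower in all 10 mutants at the preset correlation, and 5 kept the call each time (iaaA, ycdC, ycgJ, yghZ and ypdF). The histone difference in iaaA went from -0.63 to -0.35 without iaaA replicate 1, and in ypdF from -0.63 to -0.39 without ypdF replicate 2. Besides torY and yccU, histones lost the call in purH without purH replicate 2 (adjusted p = 0.0932), in crl without BW25113 replicate 1 (0.364) or 2 (0.616) or crl replicate 2 (0.210) or 3 (0.423), and in yjgU without BW25113 replicate 1 (0.170) or 2 (0.359) or yjgU replicate 2 (0.124) or 3 (0.135). These comparisons share their controls and are not independent of each other. Of the lists on social behavior, the oxygen and social feeding circuit and the list for serotonin, octopamine and tyramine did not pass in any of the 10 comparisons. Neither did neurons, heat shock response, mitochondrial stress, oxidative stress and detoxification, methionine cycle and folate, propionate breakdown and vitamin B12, lipolysis and beta-oxidation, or chemoreceptor guanylyl cyclases and sensory channels. The male list (4 genes tested) and the mitochondrial genome list (0 genes in the tables) were not tested.

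The mean of the 10 mutants was compared with BW25113 to ask what any mutant diet changed on average. Among genes with a symbol of letters and a number and a mean of at least 5 CPM, the lowest p belonged to cpr-4, at 945 CPM over the mutants and 1926 ± 672 in BW25113 (log2 fold change -1.04, SE 0.27, adjusted p = 0.539), and to the chitinase gene cht-1 (X, 3397613 to 3400017), at 25.0 against 62.9 ± 10.4 CPM. argk-1 was at 49.5 against 12.7 ± 3.31 CPM. In edgeR 0 genes were called, with 1322 at an unadjusted p under 0.05, and DESeq2 called 0.

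Values of multigene families (collagens, F-box genes, C-type lectins, cytochromes, sperm genes and histones) are uncertain where reads are shared between members, since the treatment of such reads is not given in the sources used here. Of 92 genes with coordinates that the naming rules picked, 22 overlap another protein-coding gene or an antisense RNA in the annotation. lon-3, bli-2, col-41, col-74 and col-79 lie wholly within the span of a gene on the opposite strand (ogdh-2, zyg-1, ucr-2.2, gtap-1 and dph-2), clec-266 and sdc-2 overlap kqt-1 and the antisense RNA anr-16, and fbxb-19 shares 733 bases with fbxb-18. These overlaps are between whole gene spans, and overlap of exons was not examined. Whether counting used the strand is not given in the sources used here, so it is not known whether reads of such pairs were told apart.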

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

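Chosen only after the result was seen were the tests of library scaling, of sampling time, of the depth of purH replicate 1 and of the level of ribosomal protein genes in the controls, the correlation without controls and the covariate for molting genes; the other tests in this part were chosen before.

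The F test among the 10 mutants drew attention because diet effects differed between groups by a test of the difference itself (376 genes). In 2 of 100 regroupings of the 30 mutant libraries, the real one included, as many genes passed. That share is under 0.05 and argues against chance, but only if the libraries of a group are independent samples, which is not known. The highest other count was 1049. A count several times the real one points to a structure of the samples. Which structure is not known: that draw had 2 libraries of torY and yccU in 1 group, but so did a draw with 3 calls. For the mean of the 10 mutants, 100 of 100 regroupings gave as many as the real count of 0 by edgeR (1322 at an unadjusted p under 0.05, 0 by DESeq2), which says nothing about chance, because with a real count of 0 every regrouping gives as many. The highest other count was 2933, which again points to a structure of the samples; that draw had 2 libraries of torY and yccU in the control group, but so did a draw with 27 calls. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In torY 1 of the 10 splits gave as many genes as the real one (2193, highest other 0), in yccU also 1 (385, highest other 0), and in each of the other 8 mutants all 10 did (0, highest other 0, by edgeR), which with a real count of 0 says nothing about chance.

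Larval and molting genes were higher in torY and yccU (list medians 2.27 and 1.95), and scaling of the libraries is argued against, since a factor for a whole library cancels in the list mean minus the library median, which stood above BW25113 by 2.59 in torY and 1.97 in yccU, more than the sum of the SDs of the groups (0.675 and 1.23 in the mutants, 0.371 in BW25113). A position of the sampled animals along a developmental axis that also varies within other groups is a candidate explanation. Gene slopes on the molting level within the 9 other groups correlated with torY fold changes at r = 0.735 (yccU 0.717). These values are over 14521 genes outside the larval and collagen lists. The other 8 mutants, which share the controls, had 0.386 to 0.663. Among them ycgJ had the highest molting level, 0.649 above BW25113, and r = 0.663. The level of ypdF lay 0.357 below BW25113, yet its r was 0.473, so with shared controls r did not measure position on the axis alone. Without controls torY and yccU had 0.663 and 0.650, while the 8 others had at most 0.417 in size. In each of these 8, r had the sign of the difference in molting level from the others of the 8. For example, ycgJ had r = 0.417 at a difference of 0.442, and ycdC had r = -0.361 at -0.233. The size of r did not follow the difference: ypdF had r = -0.261 at -0.708. With the molting level as a covariate the calls ended because the fold changes shrank while the errors did not. The median size in torY went from 2.64 (SE 0.718) to 0.856 (SE 0.871), with 2087 of 2193 genes keeping their sign. In yccU it went from 3.26 (SE 0.809) to 1.15 (SE 0.808), with 378 of 385. This covariate is the mean of the list that defines the pattern, and torY and yccU stood 2.76 and 2.15 above BW25113 on it. The fit therefore removes most of the difference between these groups whatever its cause, and cannot decide between explanations. An effect of diet on developmental rate and a difference in the time or batch of sampling cannot be told apart, because 5 of the 6 torY and yccU libraries lie above all 27 others and the labels give no time of sampling.

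purH replicate 1 stood apart from purH replicates 2 and 3 (correlations 0.798 and 0.846, against 0.966 between those 2). A few genes taking most of the counts is argued against, since its 10 most abundant genes held 7.64% of its counts, below the median of 10.8% over the 33 libraries. Low depth is argued against, since its total was 20.8 M, 0.931 of the median. Its TMM factor was the highest (1.90). Its levels of vitellogenins (-2.79), body muscle genes (-1.82) and oocyte and eggshell genes (-1.49), relative to the mean of the 33 libraries, were the lowest of all. Its levels of embryo genes (0.82) and neuron genes (0.11) were not extreme. In part this was shared by ycdC replicate 2 and yghZ replicate 1, with the next highest TMM factors (1.59 and 1.52). Their levels were -1.78 and -1.39 for vitellogenins, -1.26 and -0.82 for body muscle genes, and -0.90 and -0.95 for oocyte and eggshell genes. Unlike purH replicate 1, they lay below the mean for neuron genes (-0.35 and -0.41), and yghZ replicate 1 also for embryo genes (-0.23). Why these lists differed was not tested. No biological explanation was tested, and a different preparation or a wrong label stays open.

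Ribosomal protein genes were lower in 7 mutants at the preset correlation, but purH lost the call without purH replicate 1 (adjusted p = 0.294) and crl without BW25113 replicate 1 (0.102) or crl replicate 3 (0.359). Gene length bias is argued against, since in 7 of 7 the list median lay below the low quantile bound of 10000 random lists matched on exonic length. A high level in the 3 shared control libraries is a possible explanation: the BW25113 mean was the highest of the 11 groups, 0.08 above the highest mutant mean on the log2 scale, and 11 of 30 mutant libraries lay above the lowest BW25113 library. An effect of the diets stays open, untested apart from these controls. Scaling of the libraries also stays open, since it was not tested for this list. The TMM factors of BW25113 replicates 1, 2 and 3 were 0.766, 0.731 and 0.861. At the lowest factor (0.661, torY replicate 1) the list stood at 0.78 relative to the mean of the 33 libraries. At the highest factor (1.90, purH replicate 1) it stood at -0.82.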

How the results depend on the processing

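The alternatives with purH replicate 1 and yccU replicate 2 left out together, with surrogate variables (from log2 CPM or from the log of CPM plus 1) and with the molting level as a covariate, as well as each alternative of the overlap and each left-out library in the test among mutants and in the list tests, were chosen after seeing the data; the others were planned.

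With DESeq2 the count of calls was 4 in crl, 1 in purH, 2 in ycgJ and 1 in yjgU (in these 4 mutants genes at 0 in 12 to 20 of 33 libraries), 3376 in torY, 1813 in yccU (85.9% of them up, against 95.3% in edgeR), 2143 among mutants and 1730 in the overlap of torY and yccU. Of the edgeR calls, DESeq2 shared 2189 in torY and 385 in yccU. With no filter, which tests more genes, yccU had 209 and the overlap 209. RLE factors gave 2232 in torY, 393 in yccU, 360 among mutants and 389 in the overlap, and moved the median of all genes by 0.0362 (torY) and 0.0300 (yccU). With only the 6 libraries fitted, torY had 4246, yccU 2003, yjgU 523 and the overlap 1946. With purH replicate 1 and yccU replicate 2 left out together, yccU had 2907, the test among mutants 1726 and the overlap 2440. The cause was not tested for these.

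The replicate numbers were not taken to pair the samples, because the labels do not say so and only 82 of 165 same-numbered pairs had correlated deviations over 0.1 (range -0.739 to 0.751, mean 0.0733, against -0.0363 for other numbers). As a hint from the data and not the design, 17 of 33 libraries correlated best with a library of their own number, where 11 would if numbers carried nothing, so a partial sharing is not excluded. With the replicate block, yccU had 1169 calls, the test among mutants 588 and the overlap 1120; torY had 2670, each mutant with 0 calls by edgeR still had 0, and 116 list tests stayed past the threshold.

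Leaving out 1 library at a time gave 0 (without BW25113 replicate 2, by edgeR, 4017 at an unadjusted p under 0.05) to 2114 (without torY replicate 2) calls in torY, 0 (without BW25113 replicate 1, 2 or 3 or yccU replicate 1 or 3) to 2171 (without yccU replicate 2) in yccU, 0 to 1 (without ycdC replicate 3) in ycdC, and 106 (without torY replicate 1) to 957 (without yccU replicate 2) among mutants. The overlap of torY and yccU was 0 without any 1 of BW25113 replicates 1, 2 and 3, as it had to be with 0 calls in yccU. crl, iaaA, purH, ycgJ, yghZ, yjgU, ypdF and the mean of the mutants stayed at 0 by edgeR without any 1 of their libraries.

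Leaving out 1 library at a time, 108 (without BW25113 replicate 3) to 123 (without purH replicate 3) list tests passed at the preset correlation. Of the list calls, 45 stayed without each of their 6 libraries, 74 were lost at least once and 7 turned. Adjusted p in those that turned ranged from 0.00339 (without crl replicate 3) to 0.317 (turned, without crl replicate 2) for oocyte genes in crl, and from 6.55e-11 (without iaaA replicate 2) to 0.970 (turned, without iaaA replicate 1) for neuropeptides in iaaA. In purH they ranged from 5.84e-05 (without replicate 2) to 0.706 (turned, without replicate 1) for endoplasmic reticulum stress and from 2.52e-09 (without replicate 3) to 0.495 (turned, without replicate 1) for the nuclear respiratory chain. For sperm genes in ycdC they ranged from 1.01e-06 (without ycdC replicate 2) to 0.986 (turned, without ycdC replicate 1). In ypdF the oocyte genes had 0.000173 (without BW25113 replicate 1) to 0.287 (without BW25113 replicate 3) and turned at 0.138 without ypdF replicate 2. Sperm genes in ypdF had 8.40e-10 (without ypdF replicate 1) to 0.777 (turned, without ypdF replicate 3) and also turned at 0.404 without ypdF replicate 2.

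With 1 surrogate variable the result depended on the input scale: from log2 CPM torY, yccU, the test among mutants and the overlap had 0 calls by edgeR (741, 607 and 827 genes at an unadjusted p under 0.05 in the first 3). From the log of CPM plus 1 torY had 2774, yccU 31, the test among mutants 1233 and the overlap 31. With 2 or 3, on either scale, all of these had 0 by edgeR (at an unadjusted p under 0.05, with 2 and 3 from log2 CPM, 1221 and 1974 in torY, 931 and 1570 in yccU, 979 and 1507 among mutants; from the log of CPM plus 1, 969 and 1710, 779 and 1328, 844 and 1553). With the molting level as a covariate they also had 0 by edgeR (0.708%, 1.35% and 2.49% of the genes tested at an unadjusted p under 0.05). With 5, torY, yccU and the overlap had 0 by edgeR (565 and 1043 in the mutants from log2 CPM, 582 and 1098 from the log of CPM plus 1). The test among mutants then had 4 (log2 CPM) or 3 (log of CPM plus 1), crl had 2 on both scales, ycdC 1 on both scales, and iaaA and ypdF 1 each from log2 CPM and yjgU 1 from the log of CPM plus 1. The single genes were mrps-16 and ugt-54 in crl, mrps-16 in ycdC, rab-19 in iaaA, T07C4.12 in ypdF and col-92 in yjgU.

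Among the named genes, direction was kept under every alternative chosen beforehand. The following log2 fold changes turned under those chosen later, with the cause not tested. In torY with 2 surrogate variables from log2 CPM: col-74 0.24, hil-7 0.50, bas-1 -0.0043 and spe-41 -0.025. With 2 from the log of CPM plus 1: col-74 0.31, hil-7 0.57, bas-1 -0.082 and spe-41 -0.051. With 3 from the log of CPM plus 1: col-74 0.19, hil-7 0.17 and bas-1 -0.032. With 5 from log2 CPM: bas-1 -0.061, nlp-67 -0.14, nlp-33 -0.090, egg-2 0.068, spe-41 -0.23, dpy-8 -0.060, clec-229 -0.00090 and lin-42 -0.084. With 5 from the log of CPM plus 1: bas-1 -0.087, nlp-67 -0.18, nlp-33 -0.086, egg-2 0.12, spe-41 -0.23, dpy-8 -0.11, clec-229 -0.087 and lin-42 -0.081. With the molting covariate: spe-41 -0.0010 and lin-42 -0.053 in torY, and qua-1 -0.18 in yccU. In yccU with 5 from log2 CPM: col-41 -0.35, dpy-9 -0.090 and qua-1 -0.28. In yccU with 5 from the log of CPM plus 1: col-41 -0.35, dpy-9 -0.12 and qua-1 -0.25.

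Of 49 genes named in torY, 49 stayed past the threshold with DESeq2, 46 with no filter and 0 without BW25113 replicate 2. Of 25 in yccU, 25 did with DESeq2, 17 with no filter and 0 without BW25113 replicate 1, 2 or 3. Of the list tests past the threshold at the preset correlation (46 up, 73 down), 116 stayed with RLE factors and 0 with an estimated correlation (smallest adjusted p 0.962, smallest unadjusted p 0.00944); fry called 1 of 350 in its directional test and 14 in its mixed test. With 3 libraries per group, a 2-fold change was recovered for 10.0% of simulated genes in the crl comparison, so changes of that size were mostly not detectable here.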

Other observations

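The genes in the first paragraph were chosen after their values were seen, and the lists were fixed before.

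Among genes with a symbol of letters and a number and a mean of at least 5 CPM, those with the lowest p in torY by edgeR were, in this order, wrt-4, wrt-6, tag-297, nas-30, dpy-9 and cht-1. wrt-4 rose to 39.6 ± 31.8 CPM from 1.72 ± 0.442 (SD, n = 3 each; log2 fold change 4.52, SE 0.79; 75.1 in torY replicate 1, 13.8 and 29.8 in replicates 2 and 3), wrt-6 (X, 3480250 to 3483666) to 34.3 ± 18.1 from 1.38 ± 0.879 (2.39 in BW25113 replicate 1, 0.981 and 0.775 in replicates 2 and 3), tag-297 (II, 14627630 to 14630121) to 46.0 ± 18.1 from 2.93 ± 0.898, and nas-30 to 31.5 ± 8.46 from 2.94 ± 0.927. In yccU tag-297 rose by 3.82 (SE 0.71), wrt-4 by 4.00 (SE 0.77), wrt-6 by 4.07 (SE 0.80) and nas-30 by 3.19 (SE 0.63). The chitinase gene cht-1 fell in torY to 3.58 ± 1.46 CPM from 62.9 ± 10.4. All of these calls in both mutants were lost without BW25113 replicate 2, when 0 genes passed by edgeR.

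Some lists had called members in torY without passing as a list at the preset correlation. Of 29 endoplasmic reticulum stress genes 7 rose and 0 fell, and adjusted over the list alone 8 rose and 1 fell, with a median of -0.16 and a mean of 0.62 (adjusted p = 0.868). Of 30 insulin-like peptides 4 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell (adjusted p = 0.14). Of 23 methionine cycle and folate genes 3 rose and 0 fell, and adjusted over the list alone 3 rose (adjusted p = 0.797). Of 24 neuron markers 1 rose and 1 fell, and adjusted over the list alone 1 rose and 1 fell (adjusted p = 0.532).

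In a principal component analysis of log2 CPM over the 33 libraries, the first component held 45.3% of the variance and the next held 17.9%. On the second component purH replicate 1 lay highest, at 117, followed by ycdC replicate 2 (94.5) and yghZ replicate 1 (72.6).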
